A study of Arabidopsis thaliana with 30 samples.

How the data were processed

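The series holds 30 arrays of Arabidopsis thaliana seed RNA, in the wild type of ecotype Ws-0 and in lec1 mutants of the same ecotype, from plants grown under continuous light. LEC1 (LEAFY COTYLEDON1) encodes a subunit of the transcription factor NF-Y that acts during embryo development. On the ATH1 GeneChip, 20 arrays form 10 groups of 2 arrays, which the labels call biological replicates. These groups are wild-type seed 24 hours after fertilization, at the cotyledon, mature green and post-mature green stages, wild-type seedlings, and lec1-1 seed at the 24-hour, globular, cotyledon, mature green and post-mature green stages. On the older AtGenome1 GeneChip, 10 arrays form 5 groups of 2 arrays, which the labels call technical replicates, so that each group is 1 sample. The descriptions of those arrays name the ATH1 chip, while the titles and the number of probe sets are those of AtGenome1.

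Per the labels, total RNA was converted to biotinylated cRNA, hybridized to the arrays and scanned. The deposited ATH1 values are intensity values on a linear scale, made by the authors with Affymetrix Microarray Suite 5.0 and scaled on each array to a target of 500. The labels of the 2 globular-stage arrays state no scaling, and their trimmed means lay within the 500.0 to 500.1 of the other arrays. The deposited AtGenome1 values are intensity values (average differences) from Affymetrix Microarray Suite 4.0, scaled to 2500, and between 12.3% and 16.2% of the values on an array were at or below 0. The median signal of an ATH1 array lay between 176.8 and 217.4, and 58.5% to 66.4% of its probe sets reached 100. With 2 arrays per group, the number of arrays limits the precision of every value.

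The ATH1 table holds 22810 probe sets, of which 64 are controls. Gene names came from the annotation of TAIR10.1, which was used for names only. Of the ATH1 probe sets, 13513 named 1 gene, 503 named several and 8730 were left without a name. On AtGenome1, 3794 of 8297 probe sets named 1 gene. LEC1 itself is not analysed here, because no named probe set stood for it in the annotation used, so that the genotype labels were not checked against the targeted gene.

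Differences on ATH1 were tested with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with an intensity trend on log2(signal + 50). Controls were left out, as were probe sets with a signal of 100 on fewer than 2 arrays, which left 18459. All 20 arrays entered 1 model, with 10 residual and 8.64 prior degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over the probe sets of a contrast and a threshold of 0.05. The contrasts were lec1-1 minus wild type at 4 stages, the 3 differences of that effect between consecutive stages with their joint F test, and the consecutive stage steps within each genotype. Errors given with a log2 difference are moderated standard errors with n = 2 arrays per group. They rest on a spread shared over all groups, so they can understate that of late wild-type seed. Where both arrays of 1 group were below 100, the fold is given as a bound, the geometric mean of the other group over 100, written "at least N-fold". The log2 value of such a gene depends on the offset.

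Before the data were examined, 16 gene lists with 275 genes were fixed, together with the contrasts, the alternatives and the rule for naming genes. The annotation named 59 of these genes on ATH1, and 9 lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, adjusted over lists and stages. The tested lists were storage proteins (5 of 13 genes measured), oil body proteins (3 of 11), late embryogenesis abundant (LEA) proteins (17 of 26) and seed transcription regulators (3 of 20). The others were photosynthesis (10 of 47), reserve mobilisation (3 of 18), flavonoid synthesis (3 of 12), heat shock and cold or drought stress (3 of 15), and cell division (3 of 20). A result given by the name of a list covers only its measured members. Lists with fewer measured members were fatty acid and triacylglycerol synthesis, seed coat, endosperm, silique wall, trichome patterning, meristem patterning, and abscisic acid and gibberellin metabolism. For the last of these and for meristem patterning 0 members were measured. Another 9 families were chosen after reading the annotation's names and before any difference was computed. Wild-type maturation genes and seedling genes were taken from wild-type arrays that the tested genotype contrast did not use, as probe sets called and at least 4-fold higher in later seed than in early seed, or in seedlings than in seed.

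The rule named, for each genotype contrast, the 8 largest passing differences each way among probe sets of 1 gene whose lec1-1 arrays lay beyond both wild-type arrays, and up to 3 members of each list by adjusted p. For stage steps it named 4 each way, for the joint test the 5 smallest p. On AtGenome1, values were floored at 250, and a probe set counted as higher or lower by size when all 4 array-by-array ratios were at least 2-fold in 1 direction and the higher group reached 500 on both arrays. No test was run there. List medians were ranked among 10000 random lists matched on mean level.

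The labels of 8 arrays state an array lot. Whether a lot was stated was tried as a covariate, since all wild-type arrays of the cotyledon and mature green stages state a lot and no lec1-1 array of those stages does. Other alternatives were quantile normalization, scaling to the 75th percentile, an offset of 1, a floor of 100, no filter, a filter at 200, only the groups of a contrast, the replicate number as a block, no globular-stage arrays, no intensity trend, an estimated camera correlation, and leaving out each array in turn. The replicate numbers did not pair the samples, so no block entered the main model.

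The steps were tested on simulated data. For ATH1 each gene had the same spread on every array, its moderated standard deviation pooled over the groups. The larger replicate spread of late wild-type seed was thus not simulated. The changed genes were drawn from those with a wild-type level above a signal of 200, so recovery of dimmer genes was not simulated either. Among 18113 genes for the 24-hour comparison, limma recovered 59 of 100 genes made 2-fold different and 100 of 100 made 4-fold different, with 8 false calls. The counts were 72 and 100 of 100 among 18091 genes for the cotyledon stage, 59 and 99 among 18057 for mature green, and 52 and 99 among 18148 for post-mature green. Camera called 5, 1, 3 and 5 of 200 unchanged sets at an unadjusted 0.05 in the same order of stages. The simulated genes varied independently, so these counts do not test camera on lists whose genes vary together. The AtGenome1 size rule recovered 200 of 200 probe sets made 4-fold different in the 24-hour comparison. There the noise was a fixed level for all probe sets, not that of the arrays, and only bright probe sets were changed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.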

Results

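RNA levels in Arabidopsis seed were measured on 30 arrays. On ATH1, wild-type seed was sampled 24 hours after fertilization and at the cotyledon, mature green and post-mature green stages, together with wild-type seedlings. Seed of lec1-1, a mutant of the LEAFY COTYLEDON1 gene, was sampled at those 4 stages and at the globular stage. Each of these 10 groups had 2 arrays, called biological replicates in the labels. Pearson's r between the log2 values of the 2 arrays of a group lay between 0.933 and 0.982. The standard deviation of the log2 difference between replicates was 0.649 in post-mature green wild type and 0.612 in mature green wild type, against 0.328 to 0.538 in the other groups. The 20 highest probe sets held 2.83% to 8.57% of the total signal of an array. On AtGenome1, wild-type seed at 24 hours, mid-maturation and late maturation and lec1 seed at 24 hours and mid-maturation were each measured as 1 sample on 2 arrays. LEC1 itself is not analysed here, so the genotype labels rest on the deposit alone.

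The series asks how loss of LEC1 changes seed gene activity through development. Few differences between lec1-1 and wild type passed the test early, and many passed late. At 24 hours 22 probe sets passed, 1 higher and 21 lower in lec1-1, and at the cotyledon stage 131 passed, 12 higher and 119 lower. At the mature green stage 5297 passed, 2902 higher and 2395 lower, which is 28.7% of the 18459 tested. At the post-mature green stage 8142 passed, 4366 higher and 3776 lower, which is 44.1%. Of these, 1723 higher and 1374 lower at mature green, and 2975 higher and 2208 lower at post-mature green, differed at least 2-fold. The numbers with an unadjusted p under 0.05 were 823 at 24 hours and 1633 at the cotyledon stage. The model shares each gene's spread over all groups, while late wild-type replicates varied most. Late differences can thus pass too easily and early ones too rarely. Fits of only the groups of a contrast called more at 24 hours and the cotyledon stage and fewer at mature green. The order of these stages stayed, as given in the part on processing. With the stated array lot as a covariate, 16, 83, 2974 and 7363 probe sets passed in the order of stages. Within the arrays that share a lot statement, 7 passed at 24 hours (without lec1-1 replicate 2) and 6983 at post-mature green (without wild-type replicate 1). The arrays kept at post-mature green share only a missing statement, which need not mean the same lot. At the cotyledon and mature green stages no lec1-1 array states a lot and every wild-type array does, so lot and genotype cannot be told apart there. Quantile normalization and scaling to the 75th percentile moved the share of higher calls by less than 10 percentage points in each of the 4 comparisons.

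**Figure D1:**
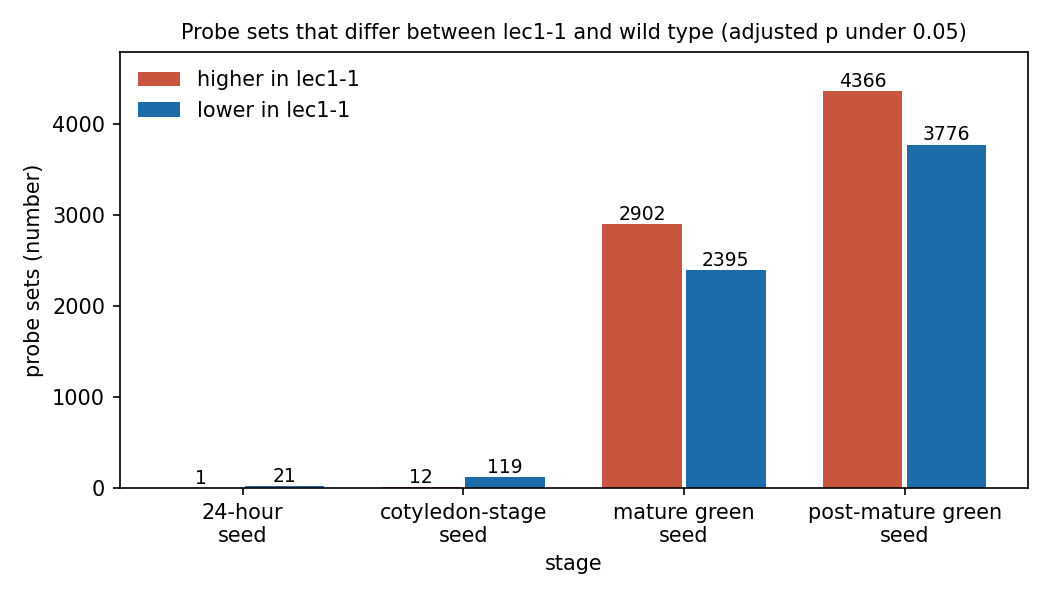
Number of ATH1 probe sets with a difference between lec1-1 and wild type at adjusted p under 0.05, by seed stage, with bars for higher and lower in lec1-1. The sum rises from 22 at 24 hours and 131 at the cotyledon stage to 5297 at mature green and 8142 at post-mature green.

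At 24 hours after fertilization, the largest difference was in AT4G22050, of the aspartyl protease family, with a mean signal of 2583 in wild type and 41.4 in lec1-1, at least 25.7-fold lower (adjusted p = 0.000231). A P-type ATPase gene, AT3G27870, was at least 6.33-fold lower, and the glycosyltransferase gene AT2G13290 at least 4.02-fold lower. DFR (AT5G42800), whose enzyme makes precursors of anthocyanins and seed coat tannins, was lower by -1.96 ± 0.26 log2, from 1914 to 455.3. The pectin methylesterase inhibitor gene AT1G56100 was lower by -2.60 ± 0.44, the proteinase inhibitor gene AT2G38900 by -2.16 ± 0.30 and AT2G17710 by -1.29 ± 0.18. AT1G08940 was at least 3.17-fold lower. The single higher call, AT2G23330, was up by 1.23 ± 0.23 (adjusted p = 0.0391). It did not pass by limma after quantile normalization (1.07, adjusted p = 0.157) or with the lot covariate (1.23, 0.139). Nor did it pass with any 1 array left out, where the difference was 1.18 to 1.28.

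The 24-hour count depended on single arrays. It was 5 without wild-type replicate 1, 11 without wild-type replicate 2, 11 without lec1-1 replicate 1 and 7 without lec1-1 replicate 2. AT4G22050, AT3G27870 and AT2G13290 passed with each array left out. Without wild-type replicate 1, the adjusted p was 0.0575 for DFR, AT1G08940 and AT2G17710, 0.103 for AT2G38900 and 0.104 for AT1G56100. Without lec1-1 replicate 2 it was 0.0543 for DFR and AT2G38900, 0.0665 for AT2G17710 and 0.373 for AT1G56100. Without lec1-1 replicate 1 it was 0.0502 for AT1G08940 and 0.0681 for AT1G56100, and without wild-type replicate 2 it was 0.0626 for AT2G17710 and 0.252 for AT1G56100. No gene list passed at 24 hours. The flavonoid list had the smallest adjusted p (0.0575), with a median of -0.09 and a mean of -0.55, and 1 of 3 genes, DFR, passing over all probe sets and adjusted over the list alone. BAN, a seed coat tannin gene, lay lower by -1.52 and did not pass (adjusted p = 0.119).

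At the cotyledon stage, a glycine-rich protein gene, AT1G04660, had a mean signal of 9159 in wild type and 116.5 in lec1-1, a difference of -5.82 ± 0.57 log2 (adjusted p = 7.3e-06). AT3G24250 was lower by -5.60 ± 0.47, and AT2G34700, which encodes a proline-rich protein of the Ole e 1 type, by -4.79 ± 0.30. The GDSL lipase gene AT5G22810 was at least 28.4-fold lower, the receptor kinase gene NCRK at least 15.6-fold lower and the papain-type protease gene AT3G54940 at least 9.25-fold lower. AT3G27870, already lower at 24 hours, was lower by -3.08 ± 0.25, and a second GDSL lipase gene, AT5G08460, by -2.91 ± 0.37. The sugar transporter gene AtVEX1 was at least 6.41-fold lower. GSTU20, a glutathione transferase gene, was lower by -2.22 ± 0.33, and the tetraspanin genes TET15 and TET10 by -2.09 ± 0.40 and -1.23 ± 0.24. Among the 12 higher probe sets were AT1G70820, at least 3.67-fold higher, and PYK10, at least 3.25-fold higher, which encodes a beta-glucosidase of the endoplasmic reticulum. AT3G19010 was at least 1.78-fold higher and CHL, a plastid lipocalin gene, higher by 0.98 ± 0.22.

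Leaving out 1 array gave 57 probe sets (wild-type replicate 1), 60 (wild-type replicate 2), 69 (lec1-1 replicate 1) and 45 (lec1-1 replicate 2) at the cotyledon stage. The calls of PYK10 (adjusted p 0.0791 to 0.184), CHL (0.247 to 0.305) and TET15 (0.0644 to 0.175) ended with any 1 of these arrays left out. TET10 did not pass without wild-type replicate 1 (0.186), wild-type replicate 2 (0.0711) or lec1-1 replicate 2 (0.255). AT3G19010 did not pass without wild-type replicate 1 (0.224) or lec1-1 replicate 2 (0.243), and GSTU20 not without lec1-1 replicate 2 (0.0513). With the lot covariate, the higher genes AT1G70820 (2.35, adjusted p = 0.0856), AT3G19010 (1.54, 0.0914), PYK10 (1.78, 0.256) and CHL (1.11, 0.184) and the lower gene TET10 (-1.10, 0.226) kept their directions and did not pass by limma.

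Of the fixed lists, oil body proteins lay lower at the cotyledon stage, with a median of -1.49 (adjusted p = 0.00176, and adjusted p = 0.266 with an estimated correlation). None of the 3 oleosin-type genes passed over all probe sets by limma, where AT3G01570 had -1.49 ± 0.35 (adjusted p = 0.0578), while 3 were lower adjusted over the list alone. Photosynthesis genes had a median of -0.37 (adjusted p = 0.0265, and adjusted p = 0.466 with an estimated correlation), with 0 of 10 passing and 1 lower adjusted over the list alone. That median was -0.24 without wild-type replicate 2 (adjusted p = 0.124) and -0.24 without lec1-1 replicate 2 (0.198). Light-harvesting and photosystem proteins, an added family, had a median of -0.44 (adjusted p = 0.000868, and adjusted p = 0.611 with an estimated correlation) with 0 of 27 passing. Storage proteins (median -0.26, adjusted p = 0.0659, 2 lower adjusted over the list alone) and cell division genes (-0.43, 0.0516, 1 lower adjusted over the list alone) did not pass. LEA proteins had a median of 0.02 with a test direction downward (adjusted p = 0.916). Seed transcription regulators had a median of 0.19 and a mean of -0.16, and flavonoid genes a median of -0.04, which was 0.02 after quantile normalization.

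At the mature green stage, THI2.1, a thionin gene, had a mean signal of 76.5 in wild type and 11455 in lec1-1, a difference of 6.63 ± 0.39 log2 (adjusted p = 7.09e-10). PYK10 was at least 78.7-fold higher, and the jacalin-type lectin gene JAL34 at least 45.9-fold higher. AT2G47780, of the rubber elongation factor family, was higher by 5.36 ± 0.26, the drought-induced gene DI21 by 5.20 ± 0.42 and the aspartyl protease family gene AT5G19100 by 5.16 ± 0.38. The GDSL lipase gene AT1G54020 was at least 16.7-fold higher. AT2G34700 was again lower, from 34247 in wild type to 667.0, a difference of -5.60 ± 0.30, and AT1G04660 was lower by -4.16 ± 0.57. AT3G25160, of the endoplasmic reticulum retention receptor family, was lower by -5.24 ± 0.35, the GDSL lipase gene AT1G71691 by -5.02 ± 0.28, and AOP3, a dioxygenase gene of glucosinolate synthesis, by -4.41 ± 0.33. AT1G53690, AT1G09500 and AT1G60970 were lower by -4.10 ± 0.32, -3.97 ± 0.32 and -3.95 ± 0.22. The count was 4075 to 4751 with 1 of the 4 arrays left out.

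Genes of seed reserves were lower at mature green. The cupin-type storage protein gene AT4G36700 fell from 32880 in wild type to 2793 in lec1-1, by -3.58 ± 0.46 log2. AT1G03890, a cruciferin-type gene, was lower by -1.89 ± 0.25 and PAP85, a vicilin-type gene, by -1.73 ± 0.27. OLEO3 was lower by -2.83 ± 0.56, the oleosin family genes AT3G01570 and AT3G18570 by -1.88 ± 0.35 and -1.66 ± 0.31, and FaTA, a thioesterase gene of fatty acid synthesis, by -2.72 ± 0.22, while FATB differed by -0.10 and did not pass. With an offset of 1, AT1G03890 (-1.90, adjusted p = 0.0752) and AT3G18570 (-1.69, 0.136) did not pass by limma. The transcription factor gene BBM was at least 2.48-fold lower and the bZIP gene EEL lower by -1.32 ± 0.23. Of storage proteins, 4 of 5 were lower, also adjusted over the list alone, with a median of -1.73 (adjusted p = 0.00526, and adjusted p = 0.266 with an estimated correlation). All 3 oil body genes were lower, also adjusted over the list alone, with a median of -1.88 (adjusted p = 0.0202, and adjusted p = 0.305 with an estimated correlation). Seed transcription regulators had 2 of 3 lower, and 3 adjusted over the list alone, with a median of -1.32 (adjusted p = 0.0202, and adjusted p = 0.266 with an estimated correlation). Wild-type maturation genes, 1278 probe sets, had a median of -0.49 with 36.9% lower and 7.98% higher (adjusted p = 2.01e-10, and adjusted p = 0.135 with an estimated correlation).

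LEA genes, whose proteins accumulate before desiccation, lay higher on balance at mature green. LEA18 had a mean signal of 1448 in wild type and 21195 in lec1-1, LEA4-5 was higher by 3.19 ± 0.44 log2 and AT4G36600 by 4.56 ± 0.42, and 6 of 17 were higher and 1 lower, also adjusted over the list alone. The median was 0.84 (adjusted p = 0.0265, and adjusted p = 0.544 with an estimated correlation). The median rested on wild-type replicate 2, without which it was -0.13 (adjusted p = 0.732), while the list mean, 1.18 with all arrays, was still 0.40 then. The median was 1.62 without wild-type replicate 1, and without lec1-1 replicate 2 it was 0.83 (adjusted p = 0.0744).

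Photosynthesis genes were lower at mature green, 7 of 10 over all probe sets and adjusted over the list alone, with a median of -1.16 (adjusted p = 0.00176, and adjusted p = 0.428 with an estimated correlation). LHCB4.3 and LHCB4.2, of the photosystem II antenna, were lower by -2.77 ± 0.22 and -1.70 ± 0.32, and PRK, an enzyme gene of the carbon reduction cycle, by -2.31 ± 0.29. The added family of light-harvesting and photosystem proteins, which includes plastid genes, had 5 of 27 higher and 6 lower (median 0.32, adjusted p = 0.714). Its plastid genes psbJ and psbZ were higher by 1.89 ± 0.26 and 1.87 ± 0.31. Wild-type seedling genes, 1928 probe sets, had a median of 0.48 with 37.2% higher (adjusted p = 1.09e-09, and adjusted p = 0.0839 with an estimated correlation).

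Other lists at mature green did not pass as sets. Reserve mobilisation had 1 of 3 lower, AIM1 at -0.54 ± 0.15, with a median of -0.42 (adjusted p = 0.38). AIM1 did not pass with the lot covariate (0.165), without wild-type replicate 2 (0.0817) or without lec1-1 replicate 1 (0.134). Flavonoid genes had 1 of 3 higher, UF3GT at 1.65 ± 0.42, and 2 adjusted over the list alone, with a median of 1.13 (adjusted p = 0.197). UF3GT did not pass with the lot covariate (1.77, adjusted p = 0.0561 by limma). It did not pass without wild-type replicate 1, where it was 0.97, or without lec1-1 replicate 1, where it was 1.42. Cell division genes had 1 of 3 higher, PRL at 1.08 ± 0.29, also adjusted over the list alone (median 0.72, adjusted p = 0.293), and PRL did not pass without wild-type replicate 1 (0.119) or lec1-1 replicate 1 (0.077). Stress genes had a median of -0.81 (adjusted p = 0.732) with 0 of 3 passing. BAN (-0.44) did not pass, nor did the endosperm genes IKU2 and AGL62 and the trichome gene TRY, each with wild-type means below 100, and ALC, a fruit opening gene, was higher by 0.95 ± 0.17.

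The added families had calls both ways at mature green, where 2902 of all 18459 probe sets tested were higher and 2395 lower. Counts near that share are no response of a family. XTH16, of the xyloglucan endotransglucosylases, was higher by 3.16 ± 0.35 and XTH19 at least 6.29-fold higher, with 2 of 7 higher and 0 lower. EXPA20 was higher by 2.18 ± 0.26 and EXPB1 lower by -2.25 ± 0.35, with 2 of 18 expansins each way. Serine carboxypeptidase-like genes had 4 of 24 higher and 2 lower, with scpl35 higher by 2.82 ± 0.31 and scpl29 by 1.79 ± 0.22. AtVEX1 was at least 6.57-fold lower, in a SWEET family with 3 of 16 lower and 0 higher. The calls of the other lower genes, SWEET2 and SWEET4, ended with the lot covariate (-0.75, adjusted p = 0.388, and -0.79, 0.249 by limma). SWEET2 was -0.42 with a floor of 100 (0.328), and SWEET4 was -0.22 without lec1-1 replicate 1. Of other genes called here, SCPL34 gave 0 and the tetraspanin gene TET9 0.19 with a floor of 100, so both calls lay at background level. TET15 was lower by -3.34 ± 0.40, with 3 of 13 tetraspanins higher and 2 lower, a median of 0.11 and a mean of -0.12. GSTU27 was higher by 3.19 ± 0.36 and GSTU16 lower by -1.70 ± 0.27, the only 2 of 10 glutathione transferases that passed. Among AGAMOUS-like genes 1 of 20 was higher, AGL26 by 1.38 ± 0.24, and 5 were lower, with AGL87 at least 2.73-fold lower. NdhL, of the chlororespiratory complex, was higher by 1.25 ± 0.33, 1 of 2 higher among 7. It did not pass without wild-type replicate 2, where it was 1.03, or lec1-1 replicate 1, where it was 0.98. The other, CRR22, was called at background level, with a difference of 0 with a floor of 100. With the lot covariate it did not pass by limma (0.83, adjusted p = 0.281).

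At the post-mature green stage, PYK10 was at least 83.6-fold higher in lec1-1, and THI2.1 rose from 65.7 in wild type to 8669, by 6.33 ± 0.39 log2 (adjusted p = 3.54e-10). AT1G74470, whose enzyme, geranylgeranyl reductase, serves chlorophyll synthesis, was higher by 5.94 ± 0.30. The cell expansion gene EXO was at least 44.5-fold higher, AT3G13175 at least 31.8-fold and the aspartyl protease gene AT1G09750 at least 30.5-fold. DI21 was higher by 5.63 ± 0.42 and scpl35 by 5.06 ± 0.31. Among the lower genes, AT2G34700 fell from 4634 to 208.1, by -4.18 ± 0.30, and AT1G04660 by -3.58 ± 0.57, so that both were lower at 3 stages. The histone family gene AT1G08170 was at least 19.3-fold lower. AT3G17130 was lower by -3.57 ± 0.31, AT5G27160 by -3.56 ± 0.35, AT3G03240 by -3.53 ± 0.31, the DREB family gene AT1G75490 by -3.47 ± 0.39 and AT1G33700 by -3.46 ± 0.35. The count was 6367 to 7359 with 1 of the 4 arrays left out.

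Photosynthesis genes were higher in lec1-1 at post-mature green, 8 of 10, with 1 lower, over all probe sets and adjusted over the list alone. The median was 2.32 (adjusted p = 0.00176, and adjusted p = 0.428 with an estimated correlation). PSBW, of photosystem II, was higher by 3.64 ± 0.22 log2 and PSAE-1, of photosystem I, by 3.04 ± 0.25, while PSAN was at least 7.33-fold higher. LHCB4.3 was the lower gene, by -1.57. Of the 27 light-harvesting and photosystem proteins, 20 were higher and 1 lower (median 1.81, adjusted p = 1.95e-05, and adjusted p = 0.537 with an estimated correlation), psbJ among the higher ones by 3.24 ± 0.26. Most of this family, 20 genes, is plastid-encoded, and of these 15 were higher and 0 lower. NdhS of the chlororespiratory complex was higher by 2.66 ± 0.23 and NdhL at least 4.76-fold higher, with 3 of 7 higher. Wild-type seedling genes, 1286 probe sets, had a median of 1.12 with 57.9% higher (adjusted p = 0.00364 with an estimated correlation).

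Maturation genes were lower at post-mature green. LEA (AT2G21490) was lower by -2.10 ± 0.26 log2, AT2G42560 by -2.53 ± 0.54 and AT1G72100 by -1.99 ± 0.42. Of 17 LEA genes, 10 were lower and 1 higher, and 10 lower and 2 higher adjusted over the list alone. Their median was -1.43 (adjusted p = 0.0202, and adjusted p = 0.531 with an estimated correlation), it was -0.88 after quantile normalization (adjusted p = 0.135), and without lec1-1 replicate 2 it was -1.28 (adjusted p = 0.0785). Storage proteins had 4 of 5 lower, also adjusted over the list alone, with a median of -1.63 (adjusted p = 0.0183, and adjusted p = 0.305 with an estimated correlation). AT1G03890 was lower by -1.88 ± 0.25, PAP85 by -1.63 ± 0.27 and AT2G28490 by -1.53 ± 0.23, but after quantile normalization PAP85 (0.13) and AT2G28490 (0.0814) did not pass, nor did the list (0.163). Oil body genes had 3 of 3 lower, also adjusted over the list alone, with a median of -1.94 that did not pass as a set (adjusted p = 0.0631) and was -0.96 after quantile normalization. AT3G18570 was lower by -2.02 ± 0.31 and AT3G01570 by -1.94 ± 0.35. With an offset of 1, AT1G03890 (-1.89, adjusted p = 0.0544), AT2G28490 (-1.53, 0.0671), AT3G18570 (-2.04, 0.0507), AT1G72100 (-2.01, 0.178) and OLEO3 (-1.43, 0.164) did not pass by limma. OLEO3 at -1.43 ± 0.56 (adjusted p = 0.0452) did not pass with any 1 array left out (0.0932 to 0.147) or after quantile normalization, where it was -0.87 (0.207). Seed transcription regulators had 3 of 3 lower, also adjusted over the list alone, with a median of -1.33 (adjusted p = 0.0265, and adjusted p = 0.266 with an estimated correlation), and did not pass after quantile normalization (-1.12, adjusted p = 0.0581) or with a floor of 100 (-0.98, 0.0541). BBM was at least 1.89-fold lower, EEL lower by -1.33 ± 0.23 and BZIP53, a bZIP activator of maturation genes, by -0.96 ± 0.18. FaTA was lower by -1.15 ± 0.22. Wild-type maturation genes, 1015 probe sets, had a median of -1.22 with 65.2% lower and 6.21% higher (adjusted p = 0.00364 with an estimated correlation).

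Flavonoid genes had 3 of 3 higher at post-mature green, also adjusted over the list alone, with a median of 2.16 that did not pass as a set (adjusted p = 0.0659). UF3GT was at least 3.38-fold and AT4G14090 at least 3.49-fold higher, and DFR, lower at 24 hours, was higher by 0.98 ± 0.26 (adjusted p = 0.0776 without lec1-1 replicate 1). The cold-regulated gene COR47 was higher by 1.55 ± 0.44. COR15A was called higher at background level, with a mean of 106.2 against 9.15, and gave 0.21 with a floor of 100 (adjusted p = 0.556). With it, 2 of 3 stress genes were higher, also adjusted over the list alone (median 1.38, adjusted p = 0.555). COR47 did not pass without wild-type replicate 2, where it was 0.73, or lec1-1 replicate 1, where it was 1.00. COR15A did not pass with any 1 array left out, where it was 1.13 to 1.63, or with the lot covariate (1.34, adjusted p = 0.0817 by limma). PRL, a replication licensing gene, was at least 3.62-fold higher, 1 of 3 cell division genes, also adjusted over the list alone (median 0.78, adjusted p = 0.293). The triacylglycerol lipase gene SDP1 was lower by -0.89 ± 0.23 and AIM1 by -0.50 ± 0.15, 2 of 3 reserve mobilisation genes, also adjusted over the list alone (median -0.50, adjusted p = 0.331). Without wild-type replicate 1 neither passed (0.0502 and 0.0646), and AIM1 not without lec1-1 replicate 2 (0.0515). ALC was higher by 1.24 ± 0.17. BAN, IKU2, AGL62 and TRY did not pass, each with a mean below 100 in at least 1 of the genotypes.

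Over all 18459 probe sets tested at post-mature green, 4366 were higher and 3776 lower, against which the counts of the added families stand. Among these families, scpl26 was higher by 3.32 ± 0.27 and scpl29 by 2.80 ± 0.22, with 9 of 24 serine carboxypeptidase-like genes higher and 3 lower (median 0.56, adjusted p = 0.0543). SWEET7 was lower by -3.13 ± 0.44 and SWEET10 by -1.96 ± 0.31, SWEET1 was higher by 1.76 ± 0.21, and 7 of 16 SWEET genes were lower and 2 higher. EXPA20 was at least 9.06-fold and EXLA2 at least 2.31-fold higher, and EXPA15 lower by -1.63 ± 0.36, with 2 of 18 expansins higher and 3 lower. XTH16 was higher by 3.13 ± 0.35 and XTH19 at least 9.55-fold higher, with 3 of 7 higher and 2 lower and a median of 0.04 that was -0.02 after quantile normalization. AGL67 was lower by -2.69 ± 0.40 and AGL95 at least 2.87-fold lower, with 5 of 20 AGAMOUS-like genes lower and 2 higher. GSTU20, lower at the cotyledon stage, was higher by 3.04 ± 0.33, and GSTU27 was at least 8.3-fold higher, with 4 of 10 glutathione transferases higher and 2 lower. TET3 was at least 2.93-fold higher and TET15 at least 3.15-fold lower, with 2 of 13 tetraspanins higher and 3 lower.

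**Figure D2:**
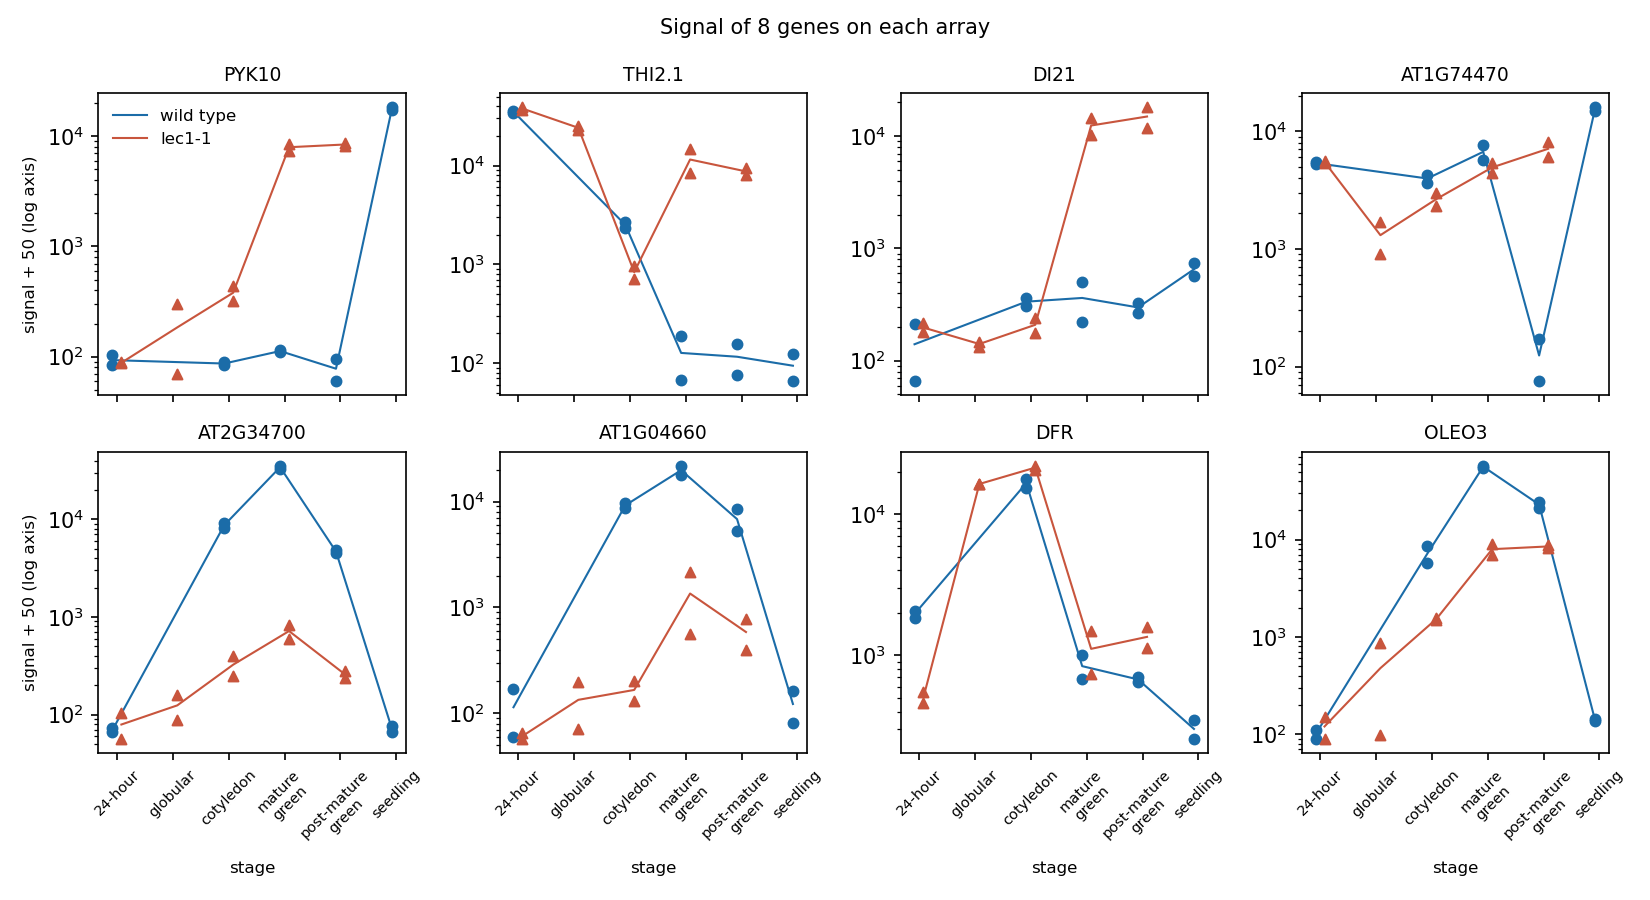
Signal + 50 (log axis) of 8 genes by seed stage, with circles for wild-type arrays, triangles for lec1-1 arrays and lines through group means; wild type has no globular group, so its line skips that stage. PYK10 and THI2.1 stand far above wild type in lec1-1 at both late stages, while AT2G34700 and AT1G04660 stand below it from the cotyledon stage on.

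The calls of both late stages overlapped. Of the higher probe sets, 1985 were shared by mature green and post-mature green, against 686.4 expected of independent lists, and of the lower ones 1349, against 489.9. Among 3604 called at both stages, 3334 had the same direction. The genotype contrasts share no array between stages, and Pearson's r of the log2 differences was 0.564 across genes, which are not independent replicates. Of the 119 probe sets lower at the cotyledon stage, AT2G34700 and AT1G04660 among them, 59 were lower at mature green (15.4 expected) and 48 at post-mature green (24.3 expected), while 16 were higher at mature green (18.7 expected) and 35 at post-mature green (28.1 expected). Across all genes r of the cotyledon-stage differences was 0.0517 with mature green and -0.0532 with post-mature green. Of the 12 higher ones, with PYK10, 9 were higher at mature green (1.89 expected) and 10 at post-mature green (2.84 expected). The 24-hour and cotyledon stages shared 1 lower probe set, AT3G27870 (0.135 expected), and 9 of the 21 lower at 24 hours were lower at mature green (2.72 expected). At 24 hours wild-type maturation genes had a median of 0.07 (adjusted p = 0.0215, and adjusted p = 0.728 with an estimated correlation) and seedling genes of 0.03 (adjusted p = 0.59). At the cotyledon stage these were -0.02 (adjusted p = 0.269) and -0.08 (adjusted p = 0.0181, and adjusted p = 0.531 with an estimated correlation). The 24-hour maturation median did not pass without wild-type replicate 1 (0.108) or lec1-1 replicate 2 (0.0686), nor the cotyledon-stage seedling median without wild-type replicate 2 (0.168) or lec1-1 replicate 2 (0.109).

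Whether the lec1-1 effect differed between stages was tested directly. LIL3:2, a light-harvesting-like gene, had effects of 0.02, -0.65, 2.35 and 4.88 log2 in the order of stages, each ± 0.19 (adjusted p = 1.76e-10 in the joint test). The plastid ribosomal protein gene AT1G29070 had 0.18, -0.50, 2.09 and 4.21, each ± 0.16. AT1G09750 had 0.72 at 24 hours, -1.85 ± 0.29 at the cotyledon stage (adjusted p = 0.00202) and 0.11 at mature green before it was at least 30.5-fold higher at post-mature green. EXO had -0.05, -0.36 and 3.63 before it was at least 44.5-fold higher. AT2G47780 had 0.03 at 24 hours, 5.36 at mature green and 3.19 at post-mature green, and did not pass at the cotyledon stage (adjusted p = 0.213), where its means were 112.7 in wild type and 45.3 in lec1-1. The joint test called 6768 probe sets. The effect differed for 58 probe sets between 24 hours and the cotyledon stage, for 3414 between the cotyledon and mature green stages and for 2940 between the mature green and post-mature green stages. The 58 were 25 to 42 with 1 array left out, lowest without lec1-1 24-hour replicate 2 (25), lec1-1 cotyledon replicate 2 (26), wild-type cotyledon replicate 1 (27) and replicate 2 (29). They were 37 and 38 without wild-type 24-hour replicate 1 and replicate 2, and 38 without lec1-1 cotyledon replicate 1.

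Photosynthesis genes changed their position against wild type between the 2 late stages. Their effect rose by 3.06 from mature green to post-mature green, in 10 of 10 genes over all probe sets and adjusted over the list alone (adjusted p = 2.32e-11, and adjusted p = 0.211 with an estimated correlation). The LEA effect fell by -2.27, with 11 of 17 lower and 14 adjusted over the list alone (adjusted p = 2.44e-07, and adjusted p = 0.422 with an estimated correlation). For single genes, 210 went from lower at mature green to higher at post-mature green and 60 the other way, with the difference itself passing. From 24 hours to the cotyledon stage the oil body effect fell by -1.70 (adjusted p = 0.000928, and adjusted p = 0.211 with an estimated correlation), with 0 of 3 passing by limma, where 58 probe sets passed, and 3 adjusted over the list alone. The photosynthesis effect fell by -0.59 over the same step (adjusted p = 0.00687, and adjusted p = 0.554 with an estimated correlation). From the cotyledon to the mature green stage the effect fell for storage proteins by -1.63 (adjusted p = 0.0403, and adjusted p = 0.481 with an estimated correlation) and for seed transcription regulators by -1.38 (adjusted p = 0.0339, and adjusted p = 0.277 with an estimated correlation). It also fell for photosynthesis genes, by -0.80 (adjusted p = 0.0292, and adjusted p = 0.632 with an estimated correlation), and rose for LEA genes by 0.51 (adjusted p = 0.0403, and adjusted p = 0.633 with an estimated correlation). Serine carboxypeptidase-like genes (0.50, adjusted p = 0.0335, and adjusted p = 0.622 with an estimated correlation) rose in effect from mature green to post-mature green.

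**Figure D3:**
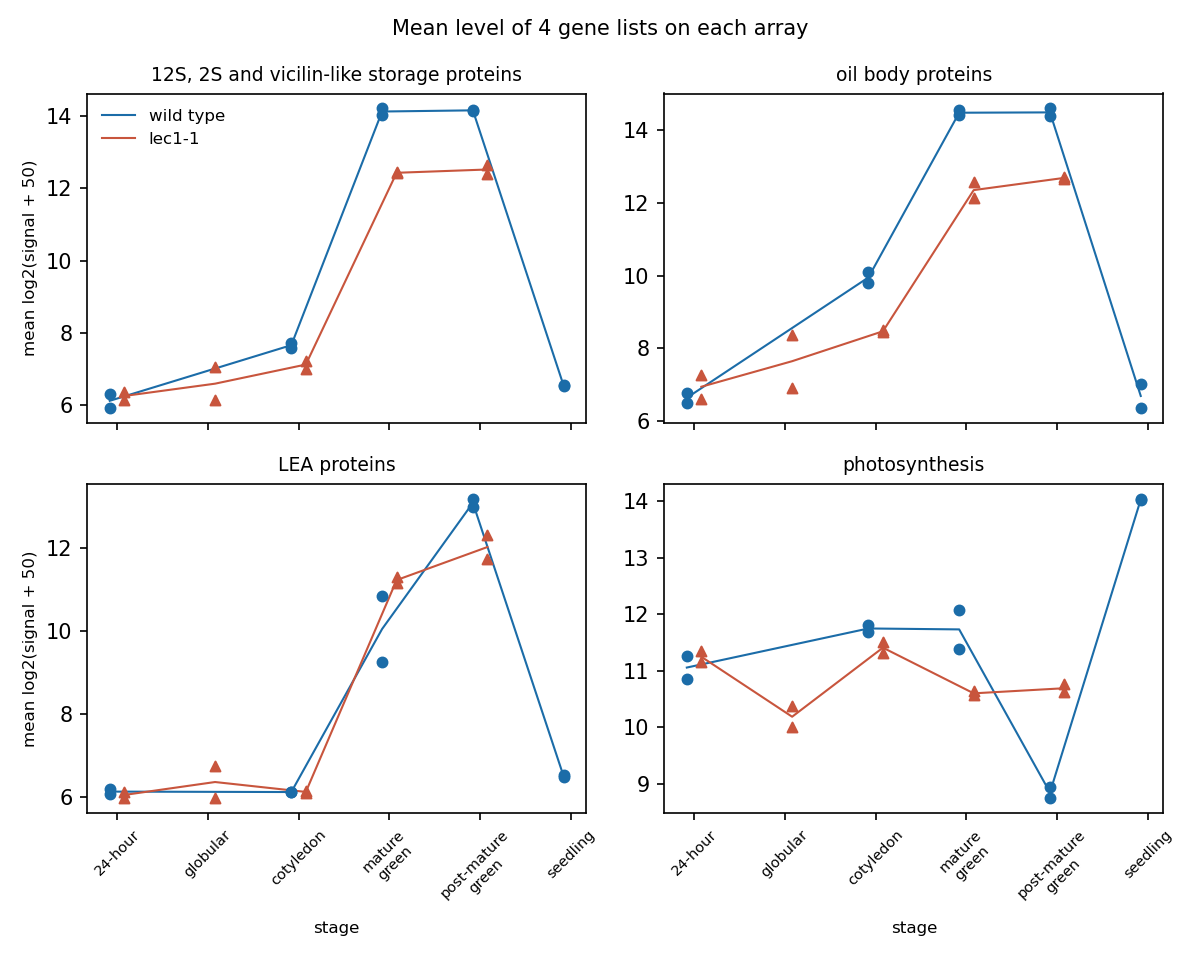
Mean log2(signal + 50) of the measured members of 4 gene lists on each ATH1 array by seed stage, with circles for wild type, triangles for lec1-1 and lines through group means; wild type has no globular group. From mature green to post-mature green, photosynthesis genes fall in wild type (median step -2.87) and not in lec1-1 (0.00), and LEA genes rise by 2.77 in wild type and 0.46 in lec1-1.

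Wild-type development gave the background for these differences. From 24 hours to the cotyledon stage, 2237 probe sets rose and 2260 fell, with AT5G38170 at least 290.8-fold and AT5G38160 at least 233.1-fold up, both of the lipid transfer protein family, and AT1G02190 at least 71.2-fold and JAL23 at least 31.9-fold down. AT2G34700 rose at least 86.5-fold and AT5G38180 at least 66.8-fold, and AT5G44630 fell at least 46.0-fold and AT4G21630 by -5.51 ± 0.30. The oil body list rose by 2.68 (3 of 3, also adjusted over the list alone, adjusted p = 0.00291, and adjusted p = 0.124 with an estimated correlation). From the cotyledon to the mature green stage 2653 rose and 3364 fell. AT1G03890 rose at least 455.7-fold, PAP85 at least 490.9-fold, AT2G28490 at least 505.2-fold and AT1G04560 at least 444.4-fold. GILT fell by -7.70 ± 0.41, AT1G56100 by -7.26 ± 0.44 and AT5G47350 by -6.81 ± 0.23, and AT3G49270 at least 73.3-fold. Storage proteins rose by a median of 8.77 (5 of 5, adjusted p = 1.86e-08), oil body proteins by 4.94 (3 of 3, adjusted p = 0.000366) and LEA proteins by 3.94 (12 of 17, adjusted p = 2.48e-10), with the same numbers adjusted over the list alone. With an estimated correlation the adjusted p were 0.0658, 0.123 and 0.124. Cell division genes fell by -2.18 (3 of 3, also adjusted over the list alone, adjusted p = 0.0161, and adjusted p = 0.123 with an estimated correlation).

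From mature green to post-mature green in wild type, 3009 probe sets rose and 3520 fell. AT3G21380 rose by 6.38 ± 0.95, the maturation gene M10 by 6.34 ± 0.67, the defensin-like gene LCR67 by 5.80 ± 0.73 and AT1G17010 at least 34.4-fold. AT5G38170 fell by -5.95 ± 0.48, AT1G74470 by -5.85 ± 0.30 and AT2G26500 by -5.30 ± 0.29, and AT1G09750 at least 31.9-fold. LEA genes rose by 2.77, 16 of 17 (adjusted p = 3.57e-10, and adjusted p = 0.124 with an estimated correlation), and photosynthesis genes fell by -2.87, 10 of 10 (adjusted p = 2.57e-09, and adjusted p = 0.123 with an estimated correlation), with the same numbers adjusted over the list alone. From post-mature green seed to seedlings 5181 rose and 6008 fell. PSAN rose at least 180.2-fold, PYK10 at least 176.7-fold, AT2G45180 at least 191.4-fold and AT3G16370 by 7.30 ± 0.35. The storage protein gene AT2G28490 fell at least 700.9-fold, AT5G45690 at least 582.8-fold, AT1G03890 at least 629.7-fold and AT1G14940 at least 598.7-fold. Photosynthesis genes rose by 5.87 (10 of 10) and LEA genes fell by -7.29 (17 of 17), with the same numbers adjusted over the list alone (adjusted p = 0.123 and 0.129 with an estimated correlation).

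In lec1-1, 2472 probe sets rose and 3041 fell from 24 hours to the globular stage, a stage with no wild-type group here. AT5G62210 rose at least 103.7-fold, AT2G30810 and AT1G11590 each at least 90.7-fold, and AT2G38900 by 6.72 ± 0.30, while AT3G06220 fell at least 26.9-fold, AT4G29030 by -5.12 ± 0.34, AT1G09750 by -4.95 ± 0.29 and AT1G25275 by -4.88 ± 0.34. From the globular to the cotyledon stage 1526 rose and 1273 fell, with AT1G03920 up by 4.57 ± 0.29 and the jasmonate methyltransferase gene JMT by 4.55 ± 0.32. THI2.1 fell by -4.87 ± 0.39 and AT4G21630 by -4.72 ± 0.30, AT1G54020 at least 25.9-fold and MSRB5 at least 21.4-fold. These 2799 were 1453 without cotyledon replicate 1, 1519 without cotyledon replicate 2, 1495 without globular replicate 1 and 1952 without globular replicate 2. Photosynthesis genes fell by -1.18 into the globular stage (8 of 10, adjusted p = 0.00257, and adjusted p = 0.541 with an estimated correlation) and rose by 1.27 out of it (8 of 10, adjusted p = 9.66e-07, and adjusted p = 0.236 with an estimated correlation).

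Storage and LEA genes rose in lec1-1 too. From the cotyledon to the mature green stage 3462 probe sets rose and 3288 fell, with AT1G14950 at least 349.3-fold, AT3G02480 at least 473.2-fold, AT2G28490 at least 208.2-fold and the LEA gene AT3G15670 at least 185.0-fold up. GILT fell by -8.24 ± 0.41 and AT1G56100 by -7.55 ± 0.44, AT5G47350 at least 176.9-fold and AT3G49270 at least 91.9-fold. Storage proteins rose by 6.93 (4 of 5, and 5 adjusted over the list alone), oil body proteins by 4.02 (3 of 3) and LEA proteins by 5.47 (15 of 17), the last pair also adjusted over the list alone, with adjusted p of 0.201, 0.236 and 0.236 with an estimated correlation. From mature green to post-mature green, 229 probe sets rose and 401 fell, and the sum of 630 was 372 without mature green replicate 1, 449 without mature green replicate 2, 209 without post-mature green replicate 1 and 442 without post-mature green replicate 2. DELTA-VPE, a vacuolar processing enzyme gene of the seed coat, fell by -4.40 ± 0.24 and AT5G38170 by -3.30 ± 0.48, AT1G62210 at least 10.6-fold and AT4G13840 at least 8.52-fold. M10 rose by 3.94 ± 0.67, LCR67 by 3.80 ± 0.73 and AT1G17010 by 2.70 ± 0.28, and M17 at least 2.27-fold. LEA genes rose by 0.46, 3 of 17 and 4 adjusted over the list alone (adjusted p = 0.000715, and adjusted p = 0.639 with an estimated correlation).

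AtGenome1 gives 1 sample per group, so its differences are sizes with no test, and those of a group at the floor of 250 are lower bounds. At 24 hours AT4G22050 was lower in lec1 by -4.35 log2, from a mean of 5110 to the floor of 250, as it was lower on ATH1. DFR lay at -1.37 and BAN at -1.67, and AT2G12400, AT1G79150 and AT1G72730 were lower by -2.05, -1.80 and -1.77. AT1G12010 was higher by 5.34, AT1G62510 by 4.81, AT2G05540 by 4.74 and AT1G05340 by 4.19, with COR47 higher by 3.04 and LEA4-5 by 2.88. By size 162 of 8247 probe sets were higher and 49 lower. Across 1761 genes measured on both arrays Pearson's r with ATH1 was 0.389 and Spearman's rho 0.319, and the 2 genes called on ATH1 had the same direction. On ATH1 most calls lay the other way, with 1 higher and 21 lower, but those were called by a test and these by size, so the counts are not of the same form. On ATH1 COR47 did not pass and LEA4-5 was below 100 in both genotypes. Leaving out replica 1 or replica 2 loosens the size rule, and gave 276 and 259 higher and 319 and 161 lower.

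At mid-maturation, LEA genes were far higher in lec1 on AtGenome1, with AT3G15670 by 7.49, LEA4-5 by 7.15, LEA by 5.86, AtLEA4-1 by 5.85 and LEA18 by 5.83. Of 10 LEA genes 9 were higher by size, with a median of 5.17, above all 10000 random lists (percentile 100). Photosynthesis genes had a median of -0.43 (percentile 2.01) and storage proteins of 0.18 (79.7), with AT2G28490 at 2.41 and OLEO3 at 0.22. AT4G12870 was lower by -4.77, SAH7 by -3.34 and AT4G29620 by -3.27. THI2.1 was lower by -4.16, while on ATH1 it lay at -1.61 at the cotyledon stage, which did not pass (adjusted p = 0.0672), and was higher at mature green. In all 283 probe sets were higher and 216 lower. They were 392 and 503 without replica 1, and 436 and 407 without replica 2. Across 1725 genes r with the ATH1 differences was 0.111 at 24 hours, 0.0641 at the cotyledon stage, 0.063 at mature green and -0.116 at post-mature green, and 309 of 595 genes called at mature green (51.9%) and 357 of 883 called at post-mature green (40.4%) had the same direction. Mid-maturation is not a stage name of the ATH1 arrays.

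Within wild type on AtGenome1, 646 probe sets were higher and 643 lower at mid-maturation than at 24 hours, and 776 higher and 964 lower at late than at mid-maturation. Without replica 2 the 643 were 1007. Storage proteins rose by a median of 6.66 from mid to late maturation (percentile 99.97), LEA proteins by 6.23 with 9 of 11 higher by size (percentile 100), and 9 of 10 photosynthesis genes fell, with a median of -2.18 (percentile 0). In lec1, 592 probe sets were higher and 646 lower at mid-maturation than at 24 hours, and the 646 were 975 and 1049 without replica 1 or replica 2. There 9 of 10 LEA genes had risen already, with a median of 4.40 (percentile 100), storage proteins had a median of 4.71 (percentile 99.89), and the SWEET gene SAG29 was higher by 7.69.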

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

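Among the tests here, those of stage mismatch of the LEA and of the photosynthesis genes, of 1 wild-type mature green array, of noisier lec1-1 arrays, of the lot covariate for LEA genes at post-mature green and of plastid-encoded genes were chosen after the result was seen. Each result listed first stood out because the effect of lec1-1 differed between stages in a test of that difference. The number of probe sets was 58 for the cotyledon stage against 24 hours, 3414 for mature green against the cotyledon stage, 2940 for post-mature green against mature green and 6768 over the 4 stages together. Of the 153 genes named for a genotype comparison, 115 had an effect that differed between stages, as did 36.7% of all 18459 probe sets tested. The 153 were named by size or p at single stages on the same arrays, so their count is no support for a dependence on stage. By lists, the median difference of the effect from 24 hours to the cotyledon stage was -1.70 for oil body proteins and -0.59 for photosynthesis. From the cotyledon to the mature green stage it was -1.63 for storage proteins, 0.51 for LEA proteins, -1.38 for seed transcription regulators and -0.80 for photosynthesis. From mature green to post-mature green it was -2.27 for LEA proteins and 3.06 for photosynthesis. With an estimated correlation between genes, none of these 8 list differences passed by camera (adjusted p 0.211 to 0.633), while 1 gene or more passed singly in 6 of the 8. A test was read as excluding an explanation only where the value passed its bound by more than its spread, the standard error of the list's mean over arrays. That requirement was added after the first values were seen, and it left 2 of the lot tests open by themselves.

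Photosynthesis genes lay below wild type in lec1-1 at mature green and above it at post-mature green. Array scaling is argued against, since the stage difference was 2.96 after quantile normalization. At post-mature green the stated lot is argued against as well, since the median was 2.32 without the wild-type array that states a lot. The arrays left there share only a missing statement, which need not mean the same lot. At mature green the median was -1.31 with the lot covariate, but every wild-type array there states a lot and no lec1-1 array does. The covariate is then set by other groups, so the lot at mature green stays open. In 9 of the 10 genes both lec1-1 means lay between, or within 2-fold of, the wild-type mature green and post-mature green means, but this count restates the pattern and weighs nothing for or against a mismatch of stages. Plastid-encoded genes weigh only in part against a position of lec1-1 between those wild-type stages, since they lay 0.97 above wild type at mature green, 31 higher and 0 lower, and wild type was itself higher there than on either side (0.96 into it and -1.01 out of it), but with an estimated correlation the adjusted p was 0.372 for each of these. For the photosynthesis genes themselves a mismatch stays open, and so does a direct effect of LEC1 on them, which was not tested.

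LEA genes lay above wild type in lec1-1 at mature green and below it at post-mature green. Array scaling is argued against as the whole of the stage difference, which was -2.09 after quantile normalization, but not for the part at post-mature green. There the median went from -1.43 (spread 0.42) to -0.88 (0.41) and ceased to pass by camera (adjusted p = 0.135). Why the call ended was not tested. The part at mature green may rest on 1 wild-type array, as the median was -0.13 without wild-type replicate 2, although the list mean was still 0.40, and the lot stays open there because the median with the lot covariate was 0.41 with a spread of 0.62. At post-mature green the stated lot as the whole cause is argued against, narrowly. The median was -1.24 with the lot covariate (spread 0.49, adjusted p = 0.0257 by camera), past the bound of -0.7. Without the wild-type array that states a lot it was -1.23 with a spread of 0.54, which decided nothing. The covariate holds only whether a lot was stated, so an effect of lots that were not stated stays open. A mismatch of stages stays open, since the count of 14 of 17 genes with both lec1-1 means between, or within 2-fold of, the wild-type means restates the pattern too. Whether LEC1 acts on LEA genes directly was not tested.

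In lec1-1, 630 probe sets changed from mature green to post-mature green, against 6529 in wild type. Noisier lec1-1 arrays are argued against, since the replicate spread of lec1-1 over that of wild type was 0.879 at mature green and 0.730 at post-mature green. The model shares each gene's spread over all groups, so the larger spread of these wild-type arrays was not set against their own count. With only the groups of a step fitted, the wild-type count was lower and still above that of lec1-1, as given in the next part. Scaling is argued against as well, since after quantile normalization 691 probe sets changed in lec1-1 and 6634 in wild type, which is 10.4%. What stays open is that the 2 lec1-1 samples may lie closer together in development than the wild-type pair, or that the mutant stops short of the late program, which no value here decides.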

How the results depend on the processing

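No test in this part was chosen after a result was seen. Under the alternatives, 276 values of the total counts and of the AtGenome1 counts stayed within 1.5 times the count and 46 did not, and of the separate ATH1 counts of higher and of lower probe sets 386 did and 84 did not. Of the values of the list medians that passed between lec1-1 and wild type, 146 still passed, 28 kept the direction and did not pass, and 1 reversed. Of those of the other list medians, 873 stayed on their side of the threshold, 27 came to pass and 3 ceased to. Direction was compared only where the main result passed, so a change of sign in a result that did not pass was not counted. Named genes stayed on their side of the threshold in 4017 values, lost the call in 146 and gained it in 40. Among those called in the main model, 0 values reversed. By setting, an offset of 1 ended 21 of 287 gene results and the lot covariate 15. A floor of 100 and an offset of 1 change dim values most, which limits what can be said of genes near background. The offset of 1 also ended limma calls of bright genes. Among them were AT1G03890 at mature green (-1.90, adjusted p = 0.0752), with means of 46026 in wild type and 12245 in lec1-1, and AT2G28490 at post-mature green (-1.53, 0.0671). Both differences hardly moved from those of the main model, so the call ended and not the difference. Outside the mature green and post-mature green groups both genes had means below 100, and the model shares each gene's spread over all groups. The offset of 1 ended the calls of AT4G14090 (0.0578) and AGL67 (0.0836) at post-mature green as well. The cause was not tested for any value below, except that fits of the groups of a contrast alone or with 1 array left out hold fewer arrays. A lone array left in a group is assumed to vary like the other groups.

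With a floor of 100, the 24-hour count was 39, the cotyledon count 238 and the count for the cotyledon against the 24-hour effect 115. Seed transcription regulators at post-mature green had -0.98 (adjusted p = 0.0541) and wild-type maturation genes at 24 hours 0 (0.0101). With only the groups of the contrast, the counts were 46 at 24 hours, 680 at the cotyledon stage and 2950 at mature green, 235 and 1248 for the cotyledon and post-mature green changes of effect, 3358 for the wild-type step from mature green to post-mature green and 419 for that step in lec1-1. With the lot covariate they were 83 at the cotyledon stage and 2974 at mature green, and at the cotyledon stage photosynthesis had -0.49 (0.209) and seedling genes -0.0541 (0.699). Without the intensity trend they were 14 at 24 hours and 33 for the cotyledon change of effect. With an offset of 1, the last lec1-1 step had 387.

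List medians that no longer passed with an offset of 1 were photosynthesis at the cotyledon stage -0.38 (0.0701), at mature green storage -1.74 (0.189), oil body -1.89 (0.189), LEA 1.00 (0.216) and seed transcription regulators -1.34 (0.0616), and at post-mature green storage -1.64 (0.216), LEA -1.44 (0.216) and seed transcription regulators -1.34 (0.0665). After quantile normalization they were storage -0.66 (0.163), LEA -0.88 (0.135) and seed transcription regulators -1.12 (0.0581) at post-mature green, and maturation genes at 24 hours 0.0533 (0.0517). With an estimated correlation 11 lists no longer passed, with the medians unmoved, which were -1.49 for oil body and -0.37 for photosynthesis at the cotyledon stage. At mature green these were -1.73 for storage, -1.88 for oil body, 0.84 for LEA, -1.32 for seed transcription regulators and -1.16 for photosynthesis, and at post-mature green -1.63 for storage, -1.43 for LEA, -1.33 for seed transcription regulators and 2.32 for photosynthesis.

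With 1 array left out, counts ranged from 5 to 11 at 24 hours, 45 to 69 at the cotyledon stage, 25 to 42 for the cotyledon change of effect, 1453 to 1952 for the lec1-1 step from the globular to the cotyledon stage and 209 to 449 for its last step. Medians ranged from -0.44 to -0.24 for photosynthesis at the cotyledon stage, -0.13 (without wild-type replicate 2) to 1.62 for LEA at mature green, -1.63 to -1.23 for LEA at post-mature green, 0.0537 to 0.110 for maturation genes at 24 hours and -0.0983 to -0.0723 for seedling genes at the cotyledon stage. On AtGenome1, leaving out 1 replica gave 259 to 276 higher and 161 to 319 lower at 24 hours, 392 to 436 higher and 407 to 503 lower at mid-maturation, and 801 to 1007 lower in wild type and 975 to 1049 lower in lec1 from 24 hours to mid-maturation. Its floor of 100 gave a correlation with ATH1 at 24 hours of 0.332, and a floor of 500 gave 28 lower at 24 hours.

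Same-number replicates of both genotypes did not vary together (correlation of their deviations -0.04 to 0.13, against -0.09 to 0.18 over all 45 pairs of groups), so the numbers do not pair the samples. With the replicate block, 18, 140, 5397 and 8224 probe sets passed in the order of stages.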

Other observations

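The tests in this part were chosen after values were seen, except that of the probe sets beyond all wild-type seed stages, whose named genes were chosen after. Genes encoded in the plastid and nuclear photosynthesis genes lay on opposite sides of wild type at the mature green stage, a difference between the sets that was not itself tested. Of 69 plastid-encoded genes measured, 31 were higher in lec1-1 and 0 lower at mature green, with a median of 0.97 (adjusted p = 8.14e-11 over 24 tests by camera, and adjusted p = 0.372 with an estimated correlation). The nuclear photosynthesis genes had a median of -1.16 there, with 7 of 10 lower (adjusted p = 0.000262, and adjusted p = 0.372 with an estimated correlation). At post-mature green 56 of the 69 were higher and 0 lower, with a median of 1.83 (adjusted p = 6.41e-14, and adjusted p = 0.372 with an estimated correlation). The 20 plastid photosystem genes had medians of 0.70 at mature green, with 5 higher, and 1.66 at post-mature green, with 15 higher. At the cotyledon stage the plastid-encoded genes had a median of -0.26 (adjusted p = 0.00108, and adjusted p = 0.465 with an estimated correlation) with 0 of 69 passing singly by limma, where 1633 probe sets had an unadjusted p under 0.05. In wild type they rose by 0.96 from the cotyledon to the mature green stage, 34 up and 2 down, and fell by -1.01 to post-mature green, 34 down (adjusted p = 0.372 for each step with an estimated correlation). These medians kept their directions after quantile normalization and scaling to the 75th percentile.

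Some probe sets in lec1-1 lay beyond every wild-type seed stage sampled. At post-mature green PYK10 had a mean signal of 8362 in lec1-1, and means of 27.8 to 62.5 at the 4 wild-type seed stages, all below 100. DI21 in lec1-1 at post-mature green lay 6.95, 5.45, 5.46 and 5.63 log2 above wild type at 24 hours, the cotyledon stage, mature green and post-mature green, with a wild-type mean of 90.1 at 24 hours. JAL34, AT4G30650, AT5G19100 and AT5G55450 also lay above all 4 stages. Wild-type seedlings were not among these stages. There PYK10 had a mean of 17682 and JAL34 of 7896, above their lec1-1 means at post-mature green (4404 for JAL34). The seedling means of DI21, AT4G30650, AT5G19100 and AT5G55450 lay below those of lec1-1. AT3G15630 lay below them by -4.78, -2.63, -3.10 and -3.06, and RR22 by -3.47, -4.32, -3.80 and -2.41. In all 793 of the 8142 probe sets lay above and 370 below, and at mature green 618 and 227 of 5297 did.

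The hypothesis that the calls at post-mature green may come from a mismatch of stages alone was tested by the share of them beyond all 4 wild-type seed stages. It was 14.3%, above the 5% set as the most that a mismatch allows and below the 20% set to exclude it, so the test decided nothing for the calls as a whole. PYK10 and DI21, which came near their lec1-1 level in no wild-type seed stage sampled, are examples that a mismatch among those stages does not account for. The test left out wild-type seedlings, where PYK10 had a mean of 17682 and DI21 of 602.3.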
